A study of Mus musculus with 9 samples.

How the data were processed

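RNA was measured in mouse telencephalons of embryonic day 12.5 (E12.5). There were 5 wild-type (WT) libraries and 4 libraries from embryos with a Nestin-Cre driven double knockout of Lats1 and Lats2 (dKO). The labels state that the RNA came from 5 control and 4 dKO embryos, so each library was taken as a separate embryo. Litters were not given. Per the labels' protocols, dissociated cells were counted, the same number of cells was pelleted for each library, and a fixed volume of an ERCC mix, a set of synthetic RNAs of known concentration, was added per cell number before RNA was extracted. Libraries were then made from 350 ng of total RNA with a stranded total RNA kit and sequenced as paired reads of 100 bp. Because every library started from the same mass of RNA, a change in RNA per cell appears in the ratio of gene reads to spike-in reads and not in the total count.

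The deposited files held whole-number read counts per gene symbol, 1 file per library, with no normalization. Per the submitters' processing notes, STAR and HTSeq were used on the mm9 build; their versions, the annotation, the strand setting of the counting and any further option are not given in the sources used here. Each file listed 34590 genes, 92 ERCC spike-ins and the counter's own rows for reads outside genes, which were kept out of library sizes and tests. These rows held on average 37.7% of all reads in no gene in WT and 33.4% in dKO, 16.6% and 17.7% aligned to more than 1 place, and 6.70% and 6.71% not aligned. Wilson intervals (95%) of these shares were at most 0.016 percentage points wide on either side and covered counting error only. Reads aligned to several places were outside the gene counts, so members of near-identical families (globins, histones, ribosomal proteins with pseudogenes, cytosolic structural RNAs) may be undercounted, and overlapping or antisense genes were taken as uncertain because the strand setting was not given. The reference at hand was of another build, so no coordinates are given; it served only for older gene symbols and for transcript length and GC content.

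Counts were analysed in R 4.3.3. Genes were kept by edgeR's filterByExpr, which left 17182 genes holding 99.9% of gene counts. The RNA content per cell was the total gene count divided by the total spike-in count, compared on the log2 scale with a two-sided exact permutation test over all assignments of 9 libraries to groups of 5 and 4. Genes were tested with edgeR 4.0.16 (quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05) under 2 scalings. The per-cell fit set the library size to the total spike-in count. The relative fit used TMM normalization over genes, so that a gene is compared with the typical gene of its library. Standard errors (SE) of log2 fold changes were the fold change divided by the root of the F statistic, and CPM values, counts scaled to a common library size, were TMM-scaled and computed from the deposited counts. The estimate of spread was drawn towards the trend over genes with 28.5 prior degrees of freedom in the per-cell fit and 4.37 in the relative fit, against 7 residual ones; the p-values of the per-cell fit share the 9 spike-in totals and are not independent between genes.

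Before the data were examined, 34 gene lists were fixed, holding 856 members, of which 843 were in the files (6 under an older symbol) and 815 were tested. They covered the targeted genes, YAP/TAZ targets, Hippo components, radial glia, intermediate progenitors, neurons, the ventral lineage, S phase, G2/M, p53 targets, replication stress, ribosomal proteins, ribosome biogenesis, RNA polymerase II machinery, the Myc family, chromatin remodelling, matrix and cytoskeleton, apical junctions, Notch, Wnt, glycolysis, oxidative phosphorylation, interferon and immediate early genes, erythroid, endothelial, pericyte, microglial, choroid plexus, diencephalic and surface ectoderm markers, structural RNAs, histones and sex-linked transcripts. The 33 lists with at least 5 tested members were compared with other genes by limma 3.58.1 camera on voom values (preset correlation 0.01, and again with an estimated correlation), and by fry, which tests whether a list's genes move on balance one way, under both scalings. Lats1 and Lats2 were named first. Ranked genes were those past the threshold with a mean of at least 1 CPM and no overlap between the groups' libraries: the 10 largest rises and 10 largest falls of each fit, leaving out predicted and clone-named genes, small RNAs, Xist and Y-linked genes. Within each list, the 4 tested members with the smallest adjusted p (2 in lists with fewer than 10) were named. A few genes that these rules pick are left out of the text; further members, named where a count was 5 or fewer or where the text singles them out, were chosen after their values were seen.

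Alternatives were DESeq2 1.42.0, limma-voom, no filter or a mean count of at least 50, a tested change of at least 1.5-fold, other scalings of genes and spike-ins, removal of the 10 most abundant genes, a covariate for sex-linked expression, the replicate number as a block, and leaving out each library. The loess alternative fitted each library against the mean library on the spike-ins, in place of the cyclic loess first planned. Fits without WT libraries 2, 3 and 4, and with the share of reads in no gene as a covariate, were added after the data were seen, as was a test in which genes were called in 3 WT and 2 dKO libraries and measured in the other 4. Between libraries of a group, the chi-square of the gene counts per degree of freedom was 4.28 to 21.5, so no library was a copy of another. The scripts were tested on simulated counts for the same 17182 genes. The relative fit recovered 62% of 100 genes seeded with a 1.5-fold change and 80% of 100 seeded with a 2-fold change, with 7 false calls. The per-cell fit, given a seeded global log2 change of 0.4, returned a median of 0.46. Without any seeded change, 20 runs of the per-cell fit gave a median of 4.5 calls and at most 32.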

Results

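Total RNA was sequenced from the telencephalon, the part of the embryonic forebrain that forms the cerebral cortex and basal ganglia, of midgestation WT and Lats1/2 dKO mouse embryos. Lats1 and Lats2 are kinases of the Hippo pathway that restrain the transcriptional coactivators YAP and TAZ, and Nestin-Cre removes floxed genes in neural progenitors. The series title poses the question of whether the pathway holds back YAP/TAZ-driven output of the whole transcriptome, and ERCC spike-ins added per counted cell made RNA per cell measurable. WT libraries 1 to 5 held 12906561, 35259998, 30415369, 31245175 and 39263370 gene counts, and dKO libraries 1 to 4 held 45803152, 27490832, 34820692 and 16566763. Depth differed between the groups by less than its spread (exact permutation p = 0.833, two-sided). WT 2, 3 and 4 stood apart from the other 6 libraries by their reads in no gene, which made up 39.3% to 41.3% of all reads in them and 32.0% to 35.6% in WT 1, WT 5 and the dKO libraries. No dKO library shared this high level, so values restricted to WT 1, WT 5 and the 4 dKO libraries are given beside the counts below. The restricted fit keeps 2 of the 5 WT libraries and so has less power. A call lost in it does not by itself trace that call to WT 2, 3 and 4.

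Lats1 fell in all 4 dKO libraries. Its normalised level was 132 ± 4.55 CPM in WT (SD, n = 5) and 59.8 ± 1.07 CPM in dKO (n = 4), a relative log2 fold change of -1.15 (SE 0.04, adjusted p = 3.12e-08, edgeR), with 58.8 to 61.3 CPM in the dKO libraries and 124.7 to 136.4 CPM in the WT libraries. Per cell it fell by 0.71 on the log2 scale (SE 0.11). Lats2 was higher in dKO, at 43.4 ± 9.46 CPM (SD, n = 4) against 27.0 ± 6.18 CPM (n = 5), with a log2 fold change of 0.69 in the relative fit (SE 0.18, adjusted p = 0.0144, edgeR) and 1.12 in the per-cell fit. The deleted exons are not given in the sources used here and gene-level counts include exons outside the deleted part, so the Lats2 count does not check its label. The relative rise of Lats2 did not pass the test without WT 2, 3 and 4.

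The dKO libraries held more gene counts per spike-in count, which measures RNA per counted cell if cell number and spike-in dose were equal between tubes. Values per cell below rest on this. WT libraries gave 58.1 ± 6.10 gene counts per spike-in count (SD, n = 5) and dKO libraries 79.1 ± 5.90 (n = 4), a 1.36-fold difference (log2 0.45, SE 0.09). The groups did not overlap: the highest WT library reached 63.5 and the lowest dKO library 71.1 (exact permutation p = 0.00794, two-sided, the smallest that the assignments of 9 libraries can give). Spike-ins were also taken 1 by 1, with the TMM-scaled gene total over each. All 49 with at least 10 counts in every library gave the same direction, and for 32 of them the groups did not overlap. Over the 19 with a mean of at least 1000 counts the log2 difference ranged from 0.39 to 0.53, without overlap for 17. Reads aligned to several places rose per spike-in by 1.33-fold (25.5 ± 2.78, n = 5, to 33.9 ± 3.82, n = 4; exact permutation p = 0.0159). Reads in no gene were 58.3 ± 12.49 and 64.1 ± 7.79 per spike-in, a 1.11-fold difference within the spread (exact permutation p = 0.413). WT 1 and WT 5 against the 4 dKO libraries gave 1.36-fold for reads in genes, 1.36-fold for reads aligned to several places and 1.35-fold for reads in no gene (46.1 and 48.5 against 52.9 to 70.5), without overlap, where 15 assignments allow no exact permutation p under 0.0667.

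**Figure D1:**
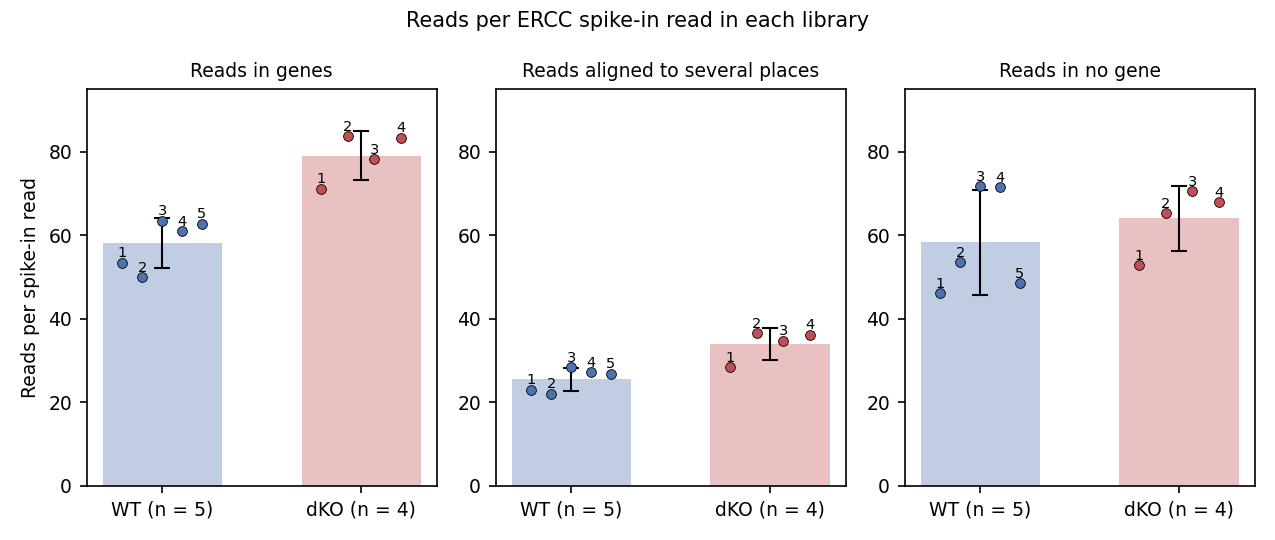
Reads per spike-in read in each library, for reads in genes, reads aligned to several places and reads in no gene. Bars are group means, error bars the SD over 5 WT and 4 dKO libraries, and points the libraries with their replicate numbers; for reads in genes the 4 dKO libraries lie between 71.1 and 83.7, all above the WT libraries.

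The rise per cell extended over most of the transcriptome. Of 17182 genes tested, 10495 rose per cell and 120 fell (edgeR, adjusted p under 0.05), and 15633 (91.0%) had a log2 fold change above 0. The median was 0.43, or 1.34-fold, with quartiles of 0.25 and 0.57. At 8345 genes (48.6%) the 2 groups of libraries did not overlap per cell, where chance gives 1.59% for a single gene. All genes share the same spike-in totals, and gene counts per spike-in already separate the groups, so the 48.6% cannot be weighed against 1.59%. Relative to the library, a scaling without spike-ins, the groups did not overlap at 22.3% of genes. The rises per cell exceeded 2-fold at 820 genes and the falls per cell at 22. Among ranked falls per cell were Slc24a4 (-1.33, SE 0.33), a cation exchanger, Dio3 (-1.32, SE 0.29), which inactivates thyroid hormone, and the serotonin receptor subunit Htr3a (-0.88, SE 0.27). Rhbdl3 (-0.79), the melanocyte enzyme gene Dct (-0.73), Lats1 (-0.71), the interneuron transcription factor Sp9 (-0.63), the transporter Slc16a14 (-0.62) and the axon guidance gene Slit1 (-0.45) were also among them. Left without WT 2, 3 and 4, the per-cell fit called 8439 rises and 43 falls, and Slc24a4, Htr3a, Dct, Slc16a14 and Slit1 did not pass. The falls also depended on single libraries: they numbered 203 without WT 1, 67 without WT 3 and 193 without dKO 4.

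**Figure D2:**
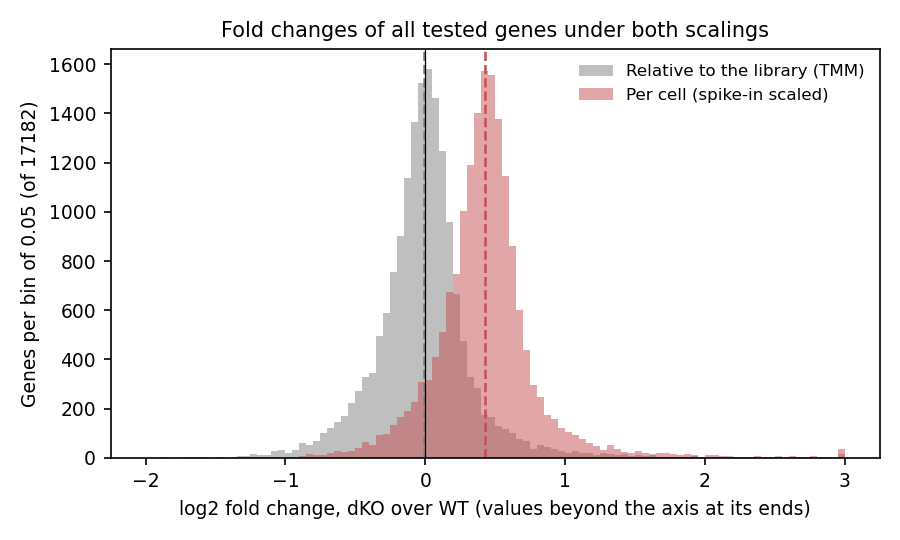
Log2 fold changes of the 17182 tested genes in the relative fit (grey) and the per-cell fit (red), as genes per bin; dashed lines are the medians. The per-cell distribution is centred at 0.43 and the relative one at -0.01.

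Changes relative to the library show which genes rose more, or less, than the typical gene; the per-cell scaling lay above it by about the per-cell median of 0.43. In these terms 2355 genes rose and 2067 fell (edgeR, adjusted p under 0.05), with 285 rises and 96 falls of at least 2-fold. All 2355 relative rises were also rises per cell. Of the 2067 relative falls, 255 were rises per cell, 115 were falls per cell and 1697 did not pass per cell. Rises thus made up 53.3% of relative calls with all libraries. Without WT 2, 3 and 4 there were 432 rises and 163 falls, so that rises made up 72.6%, and 586 of these genes were called in the same direction in both fits. A tested change of at least 1.5-fold left 182 rises and 9 falls (95.3% rises). Without WT 4 alone the relative falls numbered 1369.

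The 10 largest rises were the same genes in both fits. Thbs1, which encodes the matrix glycoprotein thrombospondin 1, went from 56.8 ± 6.75 CPM (SD, n = 5) to 755 ± 258 CPM (n = 4), a relative log2 fold change of 3.74 (SE 0.20, adjusted p = 2.75e-06, edgeR). Lrp2, the endocytic receptor megalin, went from 32.9 ± 9.21 to 358 ± 97.8 CPM (3.47, SE 0.21), and Ctgf, a secreted matricellular protein also known as Ccn2, from 6.14 ± 1.25 to 61.2 ± 28.5 CPM (3.32, SE 0.28). Steap1 (4.14, SE 0.32), the TEAD cofactor gene Vgll3 (3.72, SE 0.52) and the collagen gene Col8a1 (3.64, SE 0.40) rose from a WT mean of at most 1.45 CPM; Vgll3 did not pass without WT 2, 3 and 4. The remaining 4 were near 0 in WT. Adrb3, a beta-adrenergic receptor, had 7 counts over the 5 WT libraries and 355 over the 4 dKO libraries (27 to 174 each), a CPM ratio of 60.9 (95% exact counting interval 29.2 to 152). The intervals given here rest on counts pooled over libraries and cover counting error only, without the spread between embryos. The class II histocompatibility gene H2-Aa had 8 and 394 counts (ratio 59.1, 29.7 to 138), Crhbp, which encodes a binding protein of corticotropin-releasing hormone, 19 and 384 (24.3, 15.3 to 40.7), and the keratin gene Krt19 28 and 388 (16.6, 11.3 to 25.4).

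The largest relative falls were in Bcan, a proteoglycan of the brain matrix (7.25 ± 3.40 CPM, SD, n = 5, to 1.53 ± 0.79 CPM, n = 4; log2 -2.31, SE 0.42, adjusted p = 0.00266, edgeR), and Neb, which encodes the muscle protein nebulin (-1.80, SE 0.28). Slc24a4 (-1.73), Dio3 (-1.72), the myeloid lectin gene Siglech (-1.57), the ectodysplasin receptor gene Edar (-1.38), the retinoid-binding gene Rlbp1 (-1.31), Cntnap5c (-1.31), Htr3a (-1.30) and Hivep3 (-1.25) followed. Neb and Edar still passed without WT 2, 3 and 4, and the other 8 did not.

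**Figure D3:**
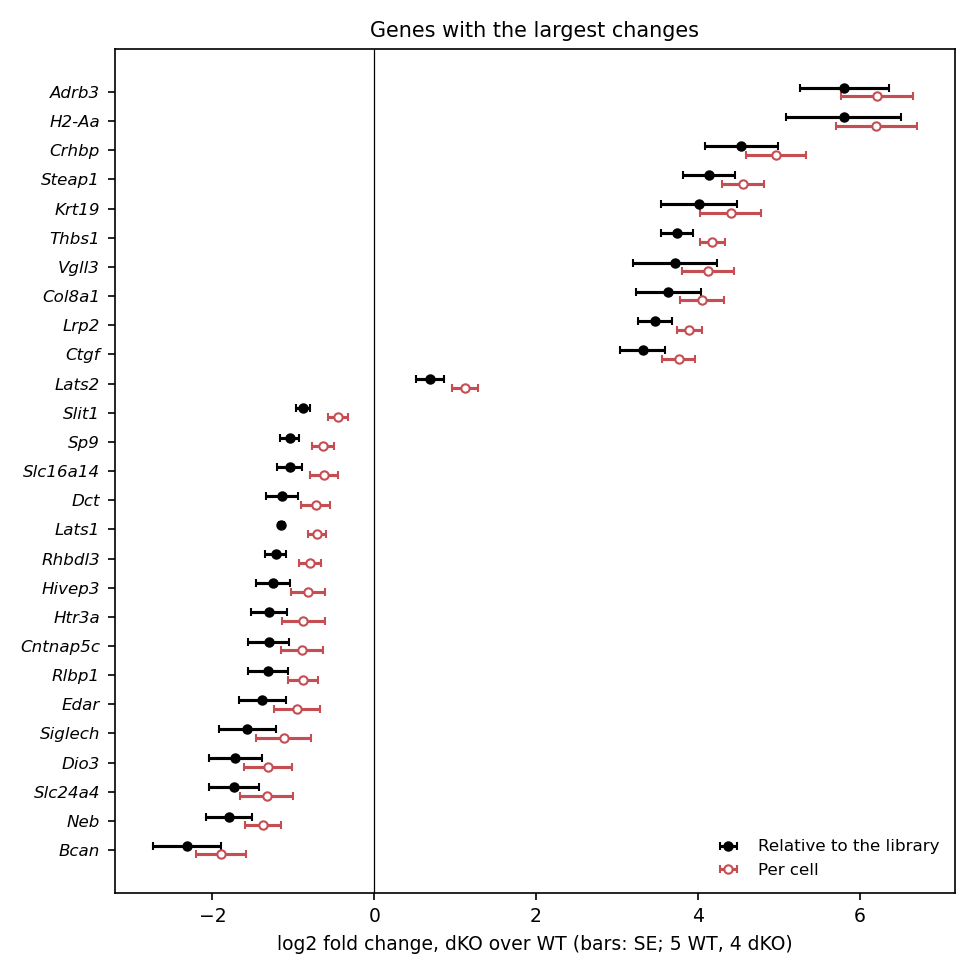
Log2 fold changes (dKO over WT, 5 and 4 libraries) of Lats1, Lats2 and ranked genes named here, relative to the library (filled) and per cell (open), with their SE. Adrb3 and H2-Aa lie farthest to the right at 5.81 and 5.80 in the relative fit, and Bcan farthest to the left at -2.31.

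Of 33 gene lists, camera called 14 higher and 3 lower than other genes with its preset correlation and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. With the preset correlation, at least 17 lists were called in 17 of 100 splits of the 9 libraries into 2 groups, the real split among them. Small camera p-values at that correlation are thus weak evidence by themselves. By fry, there were calls of 22 lists per cell, all upward, and 16 relative to the library, of which 0 passed without WT 2, 3 and 4 (smallest adjusted p = 0.0512, 13 lists at an unadjusted p under 0.05). The per-cell fry calls do not set a list apart from the general rise, since fry makes no comparison with other genes. Targets of YAP/TAZ rose as a group. Of 26 tested, 16 rose relative to the library and 0 fell, and 25 rose per cell; adjusted over the list alone, 19 rose and 1 fell in the relative fit and 26 rose per cell. The median relative log2 fold change was 0.60, or 1.04 per cell. Besides Ctgf, the clearest were Cyr61 (2.65, SE 0.14), also known as Ccn1, the Ajuba LIM gene Jub (2.19, SE 0.09) and the phosphatase gene Ptpn14 (2.26, SE 0.14). Against other genes the list was higher by camera (adjusted p = 5.16e-10), with an adjusted p = 0.323 with an estimated correlation; fry, which does not compare a list with other genes, gave an adjusted p = 0.000795, which did not pass without WT 2, 3 and 4 (0.0512). In that fit 11 rose and 0 fell, the median was 0.48, and camera still called the list higher (adjusted p = 1.97e-08). Where 0 falls are given for this list and for the cell cycle, ribosome, matrix and immediate early lists below, from edgeR with all libraries, DESeq2 and voom also called 0 falls, and at an unadjusted p under 0.05 there were 1 among these targets (Fjx1) and 0 in each of the others.

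Genes of the Hippo pathway itself went both ways. Of 28 tested, 11 rose and 5 fell relative to the library (11 and 6 adjusted over the list alone), and 23 rose per cell. The rises included Wwc2 (1.67, SE 0.12), an upstream scaffold gene, and the transcription factor genes Tead4 (1.86, SE 0.23), Tead3 (1.01, SE 0.12) and Tead1 (0.50, SE 0.06). Wwtr1, which encodes TAZ, rose by a log2 of 0.64 (SE 0.08) and Yap1 by 0.28 (SE 0.07). The falls were in the atypical cadherin genes Dchs1 (-0.51) and Fat4 (-0.38) and in the kinase and scaffold genes Taok3 (-0.25), Map4k4 (-0.20) and Nf2 (-0.12). The camera adjusted p was 0.0227, with an adjusted p = 0.336 with an estimated correlation. In the fit of 2 WT and 4 dKO libraries there were 6 rises and 0 falls (3 falls at an unadjusted p under 0.05, edgeR), the median went from 0.11 to 0.07, and the camera call was lost (adjusted p = 0.0537).

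Among genes called relative to the library, those of radial glia mostly rose, and those of intermediate progenitors, neurons and the ventral lineage fell. The lists were not tested against each other. Of 23 radial glia and neuroepithelial genes, 10 rose and 2 fell relative to the library (11 and 2 adjusted over the list alone), with a median of 0.23. The intermediate filament genes Vim (1.25, SE 0.11) and Nes (0.59, SE 0.06), the Notch effector Hes1 (0.85, SE 0.09) and Ddah1 (0.86, SE 0.09) rose, while Hes5 (-1.03, SE 0.24) and the fatty acid binding gene Fabp7 (-0.23, SE 0.05) fell. Per cell, 20 of these rose and 1, Hes5, fell (with edgeR and voom, not with DESeq2). Pax6 and Sox2, transcription factors of radial glia, had relative values of -0.05 and 0.07 that did not pass. Of 16 genes of intermediate progenitors and neurogenic commitment, 9 fell and 0 rose (13 fell adjusted over the list alone; median -0.30), among them Rcor2 (-0.32, SE 0.05), Cbfa2t2 (-0.31), the antiproliferative gene Btg2 (-0.31) and the neuronal RNA-binding gene Elavl4 (-0.46, SE 0.08). Of 27 genes of postmitotic neurons, 14 fell and 0 rose (18 fell adjusted over the list alone; median -0.28), led by the microtubule gene Dcx (-0.48, SE 0.07), Elavl3 (-0.30), the cortical transcription factor Tbr1 (-0.35) and Stmn3 (-0.27). Of 20 genes of the ventral telencephalon and GABAergic lineage, 12 fell and 0 rose (12 fell and 1 rose adjusted over the list alone; median -0.45), including Sp9 (-1.05, SE 0.12), Dlx5 (-0.66, SE 0.09), the vesicular GABA transporter Slc32a1 (-0.65, SE 0.09) and the GABA-synthesizing enzyme Gad2 (-0.57, SE 0.09).

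For the lists of intermediate progenitors, neurons and ventral genes, DESeq2 and voom called 0, 0 and 1 rises, as did edgeR at an unadjusted p under 0.05. Per cell these lineage genes did not follow the general rise. The median per-cell log2 fold change was 0.13 for intermediate progenitors and 0.15 for neurons, against 0.43 over all genes. These medians differ in sign from the relative ones because the per-cell scaling lies higher by about 0.43, which by itself shows no rise of these lists. Per cell, 2 of 16 intermediate progenitor genes (Insm1 and Tcf3) and 6 of 27 neuronal genes rose and 0 fell in the edgeR test (0 also at an unadjusted p under 0.05 and in DESeq2 and voom), where the per-cell fry test gave adjusted p of 0.246 and 0.304. In the ventral list the per-cell median was -0.02; Sp9, Dlx1 (-0.44), Dlx2 (-0.44), Lhx6 (-0.43) and Gad1 (-0.39) fell and Sp8 (0.73) rose. Relative to other genes, camera gave adjusted p of 0.00341 for radial glia, 4.45e-06 for intermediate progenitors, 6.66e-07 for neurons and 3.60e-06 for the ventral list. With an estimated correlation the adjusted p = 0.363, 0.323, 0.336 and 0.363 in that order. Left without WT 2, 3 and 4, edgeR called 7 rises and 0 falls of radial glia genes (3 falls at an unadjusted p under 0.05), and 2, 2 and 5 falls with 0 rises in the other 3 lists (0 rises also unadjusted). The neuronal median was -0.18 in this fit, and the 4 camera calls still passed.

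**Figure D4:**
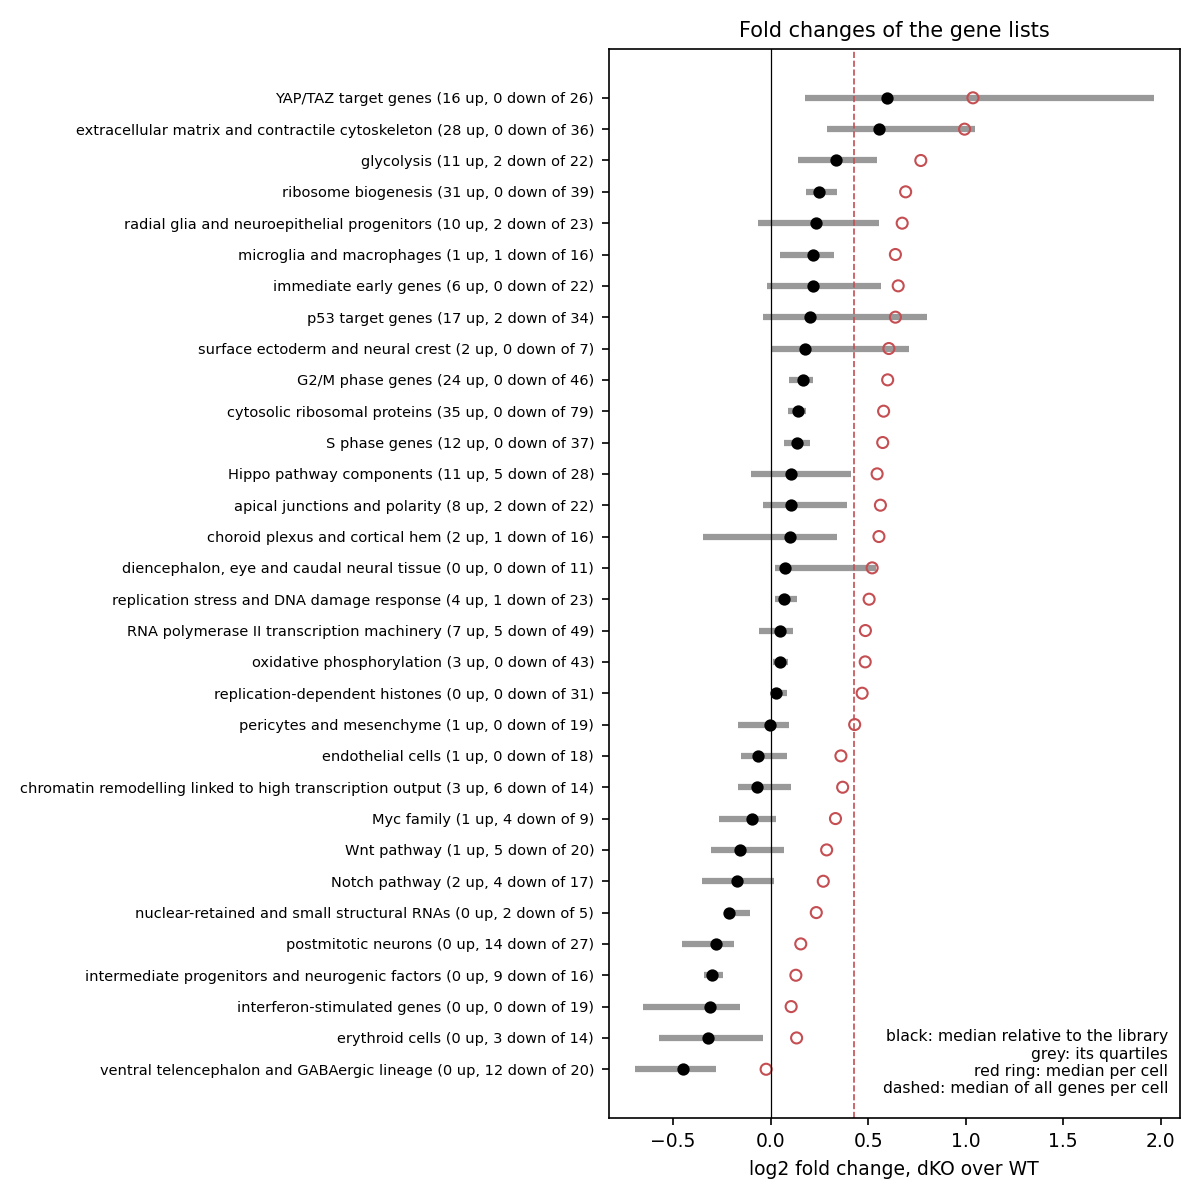
Median log2 fold change (dKO over WT) of 32 gene lists (the sex-linked list and the targeted genes are not drawn), relative to the library (black, with quartiles in grey) and per cell (red rings); the dashed line is the per-cell median of all genes at 0.43. Of those drawn, YAP/TAZ targets lie highest at 0.60 relative to the library and ventral lineage genes lowest at -0.45; neuronal and intermediate progenitor medians are below 0 relative to the library and above 0 per cell.

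Some cell cycle genes rose more than the typical gene. All 37 S phase genes and all 46 G2/M genes rose per cell. Relative to the library, 12 S phase genes rose and 0 fell (12 adjusted over the list alone; median 0.14), such as the chromatin remodeller Hells (0.32, SE 0.04), the origin recognition gene Orc1 (0.40), Usp1 (0.28) and the helicase subunit Mcm2 (0.24). Of G2/M genes 24 rose and 0 fell (26 adjusted over the list alone; median 0.16), with the cytokinesis gene Ect2 at 0.65 (SE 0.07), Hmgb2 at 0.35, the lamin B receptor Lbr at 0.33 and the kinase Aurkb at 0.35. Mki67, the common proliferation marker, had a relative value of -0.04 (SE 0.06) that did not pass. The camera adjusted p was 2.04e-05 for S phase and 2.62e-09 for G2/M, with an adjusted p = 0.531 and 0.453 with an estimated correlation. With WT 2, 3 and 4 left out, only 1 S phase gene and 2 G2/M genes rose relative to the library, the medians were 0.05 and 0.09, the S phase camera call was lost (adjusted p = 0.0554) and the G2/M call was kept (8.10e-05). At an unadjusted p under 0.05, edgeR gave 3 and 10 rises there.

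Among 34 targets of p53, 17 rose and 2 fell relative to the library (18 and 4 adjusted over the list alone), and 28 rose per cell. Sesn2 (1.59, SE 0.19), a stress-induced inhibitor of growth signalling, Ddit4l (1.13, SE 0.17) and Phlda3 (1.15, SE 0.20) rose, and Btg2 (-0.31) and Tgfa (-0.44) fell; Mdm2, a classical target, had a relative value of 0.01 that did not pass. The camera adjusted p was 0.00281, with an adjusted p = 0.531 with an estimated correlation, and without WT 2, 3 and 4 there were 2 rises and 1 fall (13 and 3 at an unadjusted p under 0.05, edgeR), a median of 0.14 against 0.20, and a camera adjusted p = 0.0120. Of 23 replication stress and DNA damage genes, 4 rose, among them the checkpoint kinase gene Chek1 (0.28), Palb2 (0.22) and Topbp1 (0.16), and Trp53bp1 (-0.19) fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0385, and adjusted p = 0.623 with an estimated correlation). In the relative edgeR fit without WT 2, 3 and 4, 0 members of this list passed (1 rise and 1 fall at an unadjusted p under 0.05), the median went from 0.07 to 0.03, and the camera call was lost (adjusted p = 0.249).

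Genes that build ribosomes rose beyond the general increase. Of 39 ribosome biogenesis genes, 31 rose and 0 fell relative to the library (35 rose adjusted over the list alone; median 0.25), and all 39 rose per cell with a median of 1.62-fold. Nop58 (0.47, SE 0.06), a core protein of small nucleolar ribonucleoproteins, Rrp12 (0.38, SE 0.05), Utp20 (0.37, SE 0.05) and Heatr1 (0.34, SE 0.04), which act in rRNA processing, were the clearest. Of 79 cytosolic ribosomal protein genes, 35 rose and 0 fell (45 adjusted over the list alone; median 0.14), such as Rpl10a (0.39), Rps18 (0.21), Rpl14 (0.21) and Rpl32 (0.18), and 77 rose per cell. The camera adjusted p was 2.52e-15 for biogenesis and 3.50e-12 for ribosomal proteins, with an adjusted p = 0.323 for both with an estimated correlation. When WT 2, 3 and 4 were left out, 10 biogenesis genes rose and 0 ribosomal protein genes passed in the relative edgeR fit (26 rose and 0 fell at an unadjusted p under 0.05), with medians of 0.23 and 0.12, and camera still called both lists (2.31e-14 and 4.46e-11).

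The transcription machinery rose per cell by a median close to the 1.34-fold of all tested genes, of which 61.1% were called up. Its members went both ways relative to the library. Of 49 RNA polymerase II machinery genes 45 rose per cell (median 1.40-fold), while relative to the library 7 rose and 5 fell (8 and 5 adjusted over the list alone; median 0.05, camera adjusted p = 0.235, fry adjusted p = 0.00722 upward, but 0.0659 under upper-quartile scaling, 0.0522 without WT 4, and 0.292 with a median of 0.01 without WT 2, 3 and 4). The mediator subunit Med14 (0.26), the kinase Cdk7 (0.28) and Gtf2e2 (0.21) rose, and Polr2a (-0.25), which encodes the largest subunit of the polymerase, Ep300 (-0.22), Crebbp (-0.22), Ccnt2 (-0.15) and Med23 (-0.13) fell. In the Myc family of 9 genes, Mycn rose (0.29, SE 0.09) and the antagonists Mxd3 (-0.41), Mxi1 (-0.27), Mnt (-0.27) and Mxd1 (-0.19) fell relative to the library (the same counts adjusted over the list alone; camera adjusted p = 0.110, and 0.0315, lower, without WT 2, 3 and 4; fry adjusted p = 0.00366 downward, and 0.0512 without them); per cell Myc, Mycn, Mycl1, Max and Mlx rose. Of 14 chromatin remodelling genes tied to high transcriptional output, Ruvbl2 (0.22), Ruvbl1 (0.18) and Chd1 (0.18) rose and 6 fell, among them Chd8 (-0.15) and Smarca4 (-0.19), relative to the library (4 and 6 adjusted over the list alone; camera adjusted p = 0.380), and 12 rose per cell. The relative edgeR fit without WT 2, 3 and 4 called 2 rises and 0 falls in the polymerase list and 0 genes in the Myc and chromatin lists. At an unadjusted p under 0.05 it gave 8 rises and 4 falls, 1 and 4, and 2 and 4.

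Extracellular matrix and contractile cytoskeleton genes rose strongly. Of 36 tested, 28 rose and 0 fell relative to the library (29 rose adjusted over the list alone; median 0.55), and 34 rose per cell with a median of 1.99-fold. Besides Thbs1, the tropomyosin gene Tpm1 (2.34, SE 0.21) and the matricellular gene Sparc (1.44, SE 0.09) rose. The camera adjusted p was 4.60e-14, with an adjusted p = 0.323 with an estimated correlation, and 13 rose and 0 fell without WT 2, 3 and 4, where camera still called the list (2.31e-14). Of 22 apical junction and polarity genes 8 rose and 2 fell (the same counts adjusted over the list alone): Cldn12 (2.18, SE 0.16), the apical determinant Crb2 (0.92, SE 0.08), Mpp5 (0.72, SE 0.08) and Tjp1 (0.50, SE 0.06) were among the rises, and Crb1 (-0.75) and Prkcz (-0.32) fell. Its camera adjusted p was 0.0229, with an adjusted p = 0.363 with an estimated correlation. That call was lost when WT 5 was left out, and 6 rose and 0 fell without WT 2, 3 and 4 (2 falls at an unadjusted p under 0.05, edgeR), with the camera call kept (0.00731). Of 22 immediate early genes 6 rose and 0 fell (6 adjusted over the list alone), namely the AP-1 family genes Atf3 (2.94, SE 0.33), Fosl2 (2.15, SE 0.22), Jun (0.53) and Jund (0.23), with Klf6 (0.72) and Dusp6 (0.54). Its camera adjusted p of 0.0186 (adjusted p = 0.453 with an estimated correlation) was lost without WT 2, 3 and 4 (adjusted p = 0.389), where 2 genes rose and the median was 0.09, against 0.21 with all libraries.

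Of 22 glycolysis genes 11 rose and 2 fell relative to the library (12 and 2 adjusted over the list alone; median 0.33). Hexokinase Hk2 (0.73, SE 0.10), the glucose transporter Slc2a3 (0.90, SE 0.13) and Eno1 (0.63, SE 0.10) rose, whereas Aldoc (-1.22, SE 0.20), an aldolase, and Pfkm (-0.15) fell. The camera adjusted p was 0.00130, with an adjusted p = 0.531 with an estimated correlation. In the fit without WT 2, 3 and 4 there were 1 rise and 1 fall, the median was 0.24, and the camera call was lost (adjusted p = 0.0598). Oxidative phosphorylation followed the typical gene more closely: 42 of 43 genes rose per cell, and Cox6c (0.17), Atp5b (0.16) and Atp5a1 (0.13) rose relative to the library (0 adjusted over the list alone in the edgeR test, 8 at an unadjusted p under 0.05, and 3 in DESeq2 and in voom; camera adjusted p = 0.0225, and adjusted p = 0.363 with an estimated correlation). This camera adjusted p was 0.0537 without WT 2, 3 and 4, at an equal median of 0.05. In the Notch list of 17 genes, Hes1 and Lfng (0.33) rose and Hes5, Mfng (-0.52), Nrarp (-0.45) and Hey1 (-0.35) fell relative to the library (2 and 6 adjusted over the list alone; camera adjusted p = 0.257). In the Wnt list of 20, Wnt5a (0.38) rose and Lef1 (-0.54), Nkd1 (-0.54), Rnf43 (-0.58), Sfrp1 (-0.20) and Wnt7b (-0.16) fell (the same counts adjusted over the list alone; camera adjusted p = 0.267). The fit without WT 2, 3 and 4 called 1 rise and 0 falls in each of these pathways (edgeR), with 6 falls in each at an unadjusted p under 0.05.

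Markers of other cell types gave few relative calls, and camera called none of their lists with all 9 libraries (adjusted p from 0.141 for erythroid and surface ectoderm genes to 0.797 for endothelial genes). Of 14 erythroid genes, the globins Hbb-b1 (-1.10), Hba-a2 (-0.69) and Hba-a1 (-0.58) fell. Single markers rose in the endothelial list of 18 (Flt1, 0.32) and in the pericyte and mesenchyme list of 19 (Ogn, 0.88). Of 16 microglial genes Mrc1 (0.65) rose and P2ry12 (-0.86) fell; of 16 choroid plexus and hem genes Bmp4 (1.09) and Foxj1 (0.47) rose and Aqp1 (-0.81) fell; and of 7 surface ectoderm and neural crest genes Grhl3 (1.26) and Erbb3 (0.85) rose. Of 11 diencephalic and caudal genes, 19 interferon-stimulated genes and 31 replication-dependent histone genes, 0 passed in the relative edgeR fit, and 7, 1 and 29 rose per cell. At an unadjusted p under 0.05 these lists had 1 rise (Irx1), 1 rise and 1 fall (B2m and Stat2) and 1 fall (Hist2h2be). DESeq2 called 1 interferon gene and voom 0, and neither called a gene of the other 2 lists. The pericyte list (median -0.01, mean 0.02) and the choroid plexus and hem list (median 0.10, mean -0.02) differed in sign between median and mean. Camera gave the sign of the median. Adjusted over the list alone, the relative counts were the same in these lists except for 0 in the endothelial list. Of 5 structural and nuclear-retained RNAs, Meg3 (-0.32) and Malat1 (-0.23) fell relative to the library (2 adjusted over the list alone). The 5 sex-linked transcripts did not pass in either edgeR fit, in DESeq2 or in voom, nor at an unadjusted p under 0.05. WT 2, 3 and 4 differed from WT 1 and WT 5 in the 5 sex-linked transcripts (median log2 difference -4.56), in erythroid genes (-0.83) and in diencephalic genes (-0.73). Leaving out WT 2, 3 and 4 therefore also changes the WT level of sex-linked transcripts, so embryo sex may contribute to the sex-linked call that follows. Without WT 2, 3 and 4, camera called the erythroid (adjusted p = 2.29e-06, median -0.81), interferon (6.45e-05), histone (0.00119), endothelial (0.0167) and sex-linked (0.00338) lists lower. Relative fry called 0 lists in that fit. With all libraries, medians of these lists as far from 0 came from 44 to 70 of 100 splits.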

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

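The tests against a few abundant genes, a few spike-ins, an unequal spike-in dose, the 3 WT libraries with many reads in no gene (for RNA per cell) and less ventral tissue, and the test with genes chosen and measured in separate libraries, were chosen after the results were seen.

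In 76 sets of values, each of 1 quantity in the libraries of 1 group, 3 held a library far from the others, and chance gives about 1 in 20 groups. The 10 most abundant genes took 6.89% of gene counts in WT 1 (95% Wilson interval 6.87% to 6.90%, counting error only) and 7.15% to 7.24% in the other WT libraries. Neb reached 6.90 CPM in dKO 3 and 4.51 to 4.76 CPM in the other dKO libraries. Sp9 was at 8.67 CPM in dKO 4 and at 13.2 to 13.7 CPM in the other dKO libraries. Reads aligned to several places, which lie outside the gene counts, rose 1.33-fold per spike-in from WT to dKO.

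The 1.36-fold rise of gene counts per spike-in was weighed against 4 technical explanations. A few abundant genes are argued against, since the genes outside the 10 most abundant had a median per-cell log2 fold change of 0.43, and a few spike-ins likewise, since 49 of 49 gave a rise. The 3 WT libraries are argued against as the whole cause: without them the fold was 1.36 and the groups did not overlap. An unequal spike-in dose or cell number per tube cannot be told apart from more RNA per cell, because it follows the groups. Reads in no gene per gene count, a ratio without spike-ins that an error of dose leaves unchanged, gave p = 0.111 (exact permutation, two-sided). Without the 3 WT libraries reads in no gene rose 1.35-fold per spike-in, close to reads in genes. An error of dose and an even rise of RNA per cell would both give this. More RNA per cell after loss of Lats1/2 thus stays a hypothesis. As many as 10615 genes were called per cell in 1 of 100 splits, the real one. The highest other gave 6759, from the split of WT 4 and the dKO libraries against the other WT libraries, which keeps the dKO libraries together. These calls all share the same spike-in totals, so the splits rank the total and do not exclude chance for single genes.

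As many as 4422 genes were called relative to the library in 1 of 100 splits, the real one. The highest other was 3590, from the split of WT 1 and the dKO libraries against the other WT libraries, which keeps WT 2, 3 and 4 together. This ranks the total and does not exclude chance for single genes. Without WT 2, 3 and 4, 586 of the 4422 genes were called, where 2 WT libraries remain and power is lower. The median effect was 78.3% of that with all libraries, and 100% of rises and 100% of falls kept their sign. The shared libraries favour these values. Genes called between WT 2, 3 and 4 and 2 dKO libraries kept a median of 44.9% of their effect (40.1% to 60.04% over the 6 choices of dKO libraries) in the 4 libraries not used to choose them, against 85.2% (55.2% to 150.3%) over 54 choices with another 3 WT libraries. The part of the relative calls that comes from these 3 libraries therefore cannot be told apart from the group difference. The 17 lists called relative to other genes were matched or passed in 17 of 100 splits (highest other 21), so chance cannot be excluded for that number. The same holds for medians of the S phase, apical junction, replication stress and immediate early lists (7, 15, 16 and 8 of 100 splits). For the 22 lists called per cell it was 1 of 100 splits, the real one (highest other 1). Those calls share the same spike-in totals, so this ranks their number and does not exclude chance for single lists.

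The lower share of neuronal, intermediate progenitor and GABAergic transcripts had a median of -0.31 over 63 genes. Transcript length and GC content are argued against as the whole cause, as the median stayed at -0.27 with their trend removed (100% of the genes had a length). The 3 WT libraries are argued against as the whole cause, at -0.30 without them (58 of 63 genes lower), though the neuronal median went from -0.28 to -0.18 and the pooled value rests more on the ventral list (-0.45 to -0.51). Less ventral tissue in the dKO samples would raise dorsal genes and so is argued against for the dorsal neuronal part only. The 16 dorsal lineage genes, 12 of them from the fixed lists, had a median of -0.29 (camera adjusted p = 0.000110, 0.127 with an estimated correlation). Most of those 12 came from lists already seen to fall, so this camera p-value describes the fall and is no independent test of it. Without the 3 WT libraries the median was -0.14. The progenitor genes Emx2 (-0.11), Lhx2 (-0.08), Pax6 and Lhx9 (both -0.05) were not past the threshold. For the GABAergic part less ventral tissue stays open. It would also lower the ventral progenitor genes described below, which had a median of -0.35 (2 of 12 fell and 0 rose, edgeR). Slower or later neuronal differentiation, more progenitors, and loss of neurons during dissociation may all give the lower share and were not tested apart.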

How the results depend on the processing

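Fits without WT 2, 3 and 4, and with the share of reads in no gene as a covariate, were chosen after the data were seen. The other alternatives were fixed before the data were examined, except that the loess used took the place of the cyclic loess first planned.

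No named gene and no list that was called with all libraries reversed its direction under the alternatives run on it. Among the 16 lists that camera did not call, the histone list went from higher (adjusted p = 0.347) to lower and called (0.00119) without WT 2, 3 and 4, the diencephalic list also changed sign there, and 4 changed sign without a call under the block (interferon, endothelial, pericyte, choroid plexus). Sign changes without a call also came with 1 library left out: the endothelial, pericyte and choroid plexus lists without WT 5, the endothelial and pericyte lists without dKO 1, the histones without dKO 2 and the endothelial list without dKO 4. With 1 library left out, genes rising per cell numbered 8879 to 11454 and relative to the library 1782 to 2456, the fold of gene counts per spike-in was 1.31 to 1.41, and 15 to 18 lists were called relative to other genes and 19 to 26 per cell. A tested change of at least 1.5-fold, a stricter criterion by construction, left 701 rises and 4 falls per cell and 182 rises and 9 falls relative to the library. The falls per cell (120) were 79 with DESeq2, 187 with no filter on low counts, 43 without WT 2, 3 and 4, 42 with the covariate, and 67 (without WT 3) to 203 (without WT 1) with 1 library left out, 193 without dKO 4. The relative counts were 432 rises and 163 falls without WT 2, 3 and 4, and 989 and 738 with the covariate, and the relative falls ranged from 1369 (without WT 4) to 2275 (without WT 1). Gene counts per spike-in kept a 1.36-fold rise without WT 2, 3 and 4 (exact permutation p = 0.0667) and a 1.39-fold rise with the replicate number as a block, which leaves out WT 5 (p = 0.125, exact permutation); both p-values are the smallest those designs allow. The block gave 10463 rises and 146 falls per cell and 1883 and 1603 relative to the library. The numbers do not pair the libraries: deviations of libraries with the same number correlated at -0.13, -0.13, -0.22 and 0.11, over genes, which are not independent replicates. With an estimated correlation, camera called 0 of 33 lists (5 at an unadjusted p under 0.05), where 17 passed with the preset one and fry called 16. Per-cell list calls by fry fell from 22 to 7 without WT 2, 3 and 4, and all 7 were among the 22, and relative fry calls fell from 16 to 0 (13 at an unadjusted p under 0.05); camera called 17 lists there, 11 of them shared and 6 gained (Myc family, interferon, erythroid, endothelial, histone and sex-linked). Without WT 1 the histones were called in the opposite direction, higher (adjusted p = 0.0383). Interferon genes were also gained without WT 2 or dKO 4, and erythroid genes without WT 4 or dKO 2. The camera calls lost without WT 2, 3 and 4 were Hippo, S phase, replication stress, glycolysis, oxidative phosphorylation and immediate early genes. Apical junctions were lost without WT 5; replication stress under upper-quartile scaling, the block, and without WT 3, WT 5 or dKO 2; and oxidative phosphorylation under upper-quartile scaling. Over named genes and alternatives, 2139 per-cell results kept their call and 96 lost it, and 2307 relative results kept it and 246 lost it. Where the construction does not show it, the cause was not tested.

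Depth and sample number limit small changes. In simulated counts the relative fit recovered 62% of 100 genes changed 1.5-fold and 80% of 100 changed 2-fold. With so few changed genes the adjusted threshold is stricter than in the data, where 4422 genes passed. These shares therefore do not give the sensitivity of the fit to the data.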

Other observations

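All gene lists in this part were written after the results had been seen, and the tests on later radial glia and early neuroepithelial genes were set before their own values were seen; adjusted p-values cover these added lists.

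Genes of amino acid and protein stress responses rose relative to the library. Of 23 genes of the amino acid response, targets of the transcription factor ATF4 in amino acid supply and in stress responses, 19 rose and 1 (Vldlr, -0.25) fell, with a median log2 fold change of 0.42 (camera adjusted p = 8.67e-10, 0.170 with an estimated correlation, and 2.90e-10 without WT 2, 3 and 4). Asparagine synthetase Asns rose by a log2 of 1.22 (SE 0.16), Phgdh and Psat1 of serine synthesis by 0.76 and 1.07, and the glutathione-degrading enzyme Chac1 by 2.09 (SE 0.31). Sesn2 (1.59) is also a member of the p53 list. Of 16 genes of the unfolded protein response 14 rose and 0 fell (edgeR; also 14 and 0 at an unadjusted p under 0.05 and with DESeq2 and voom), with a median of 0.41 (camera adjusted p = 4.04e-10, 0.170 with an estimated correlation). The chaperone genes Hspa5 (0.71, SE 0.10), Hsp90b1 (0.48), Creld2 (0.59) and Hyou1 (0.42) were among them. Of 20 sterol biosynthesis genes 12 rose and 0 fell (edgeR; 15 and 0 at an unadjusted p under 0.05, 13 and 0 with DESeq2, 12 and 0 with voom), with a median of 0.22 (camera adjusted p = 9.52e-08, 0.127 with an estimated correlation), among them Sc4mol (0.55), Idi1 (0.49) and Insig1 (0.37). Without WT 2, 3 and 4 the medians were 0.46, 0.32 and 0.22 in the same order. These lists were chosen with the genes' values in view, so their p-values are descriptions and exclude no chance.

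Other added lists moved less evenly. Of 12 simple epithelial keratin and claudin genes, 6 of them also in the junction list, Cldn12, Krt19 and Cldn9 (1.33) rose and 0 fell (edgeR; the same at an unadjusted p under 0.05 and with DESeq2 and voom), but the list did not pass (camera adjusted p = 0.118). Of 12 ventral progenitor genes, 6 of them also in the ventral list, 2 fell, 1 of them Helt (-1.30), and 0 rose (edgeR; 3 and 0 at an unadjusted p under 0.05, 2 and 0 with DESeq2 and voom; median -0.35, camera adjusted p = 0.0175, and 0.411 with an estimated correlation), and chance cannot be excluded, since 11 of 100 splits gave a median as far from 0 (highest other 0.52). Of 3 tested class II histocompatibility genes H2-Aa (5.80) and H2-Ab1 (1.38) rose.

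The rise of Hmga2 (log2 1.22, SE 0.21), a gene of early neural stem cells, led to the hypothesis that the dKO telencephalon keeps an earlier neuroepithelial state. Of 14 early genes without Hmga2, 9 rose and 2 fell (Pou3f1, -0.38, and Rgma, -0.33), with a median of 0.32 and a camera p = 0.000152 (0.170 adjusted with an estimated correlation). Without WT 2, 3 and 4 the median was less, at 0.15 (adjusted p = 0.00430). A median as far from 0 came from 4 of 100 splits (highest other 0.35). Epha2 (1.93, SE 0.14), Lin28a (2.47, SE 0.39), Trim71 (1.33), Mest (1.06) and Hmga1 (0.45) were among the rises. An earlier state may explain this rise, and direct regulation of these genes by YAP/TAZ, which these data do not separate from it, stays open.

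Falls such as those of Bcan, Rlbp1, Aldoc and Hes5 led to the hypothesis that genes of later radial glia and astroglia are lower as a group. Of 28 such genes, with those that led to the hypothesis left out, 6 rose, with Clu at 2.20 (SE 0.27) and Mlc1 at 0.42, and 5 fell, with Ndrg2 at -1.02 (SE 0.19), Ptprz1 at -0.53 and Ttyh1 at -0.36. The median was -0.17 and camera gave an adjusted p = 0.138, so the hypothesis was not decided: only the real 1 of 100 splits gave a median as far from 0 (highest other 0.15), but without WT 2, 3 and 4 the median was 0.01.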
